A study of Caenorhabditis elegans with 8 samples.

How the data were processed

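RNA was measured in whole N2 animals (the standard wild-type strain of Caenorhabditis elegans) exposed to the pathogen Pseudomonas aeruginosa PA14 in a slow-killing assay, in which worms feed on a bacterial lawn and become infected through the gut. Total RNA was extracted with Trizol, and libraries were built after poly(A) enrichment. There were 8 libraries. On PA14, 1 library was made at 4 h, 1 at 8 h, 2 at 12 h, 1 at 17 h and 2 at 22 h, and 1 library was made at 22 h on Escherichia coli OP50, the usual food of the worm. The labels do not say whether the paired libraries came from separate cultures, so p-values measure only the spread between these samples.

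The deposited table held FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each gene and library, computed by the authors with TopHat2 2.0.7 and Cufflinks per the submitters' processing notes. A lower and an upper bound were deposited beside each FPKM, of a level that the labels do not state. The version of Cufflinks, the genome build and the annotation are not given in the sources used here, and neither is any scaling between libraries. All 24 measurement columns were read, and the bounds entered no test. The table had 27744 rows. Of these, 25476 carried 1 gene name and 2268 joined the names of several neighbouring genes, and the joined rows took a median of 37.6% of the FPKM of a library. There were 287 names on more than 1 row, covering 597 rows, and these rows stayed separate in the tests. In 9 rows the lower bound was an overflow value beside an FPKM of 0, among them vit-2 and vit-6, which were at 0 in all libraries, and vit-3, vit-4 and vit-5, which were at 0 on OP50. Gene positions were taken from the WBcel235 annotation by name, which matched 24269 of the single names, and the positions printed are in that build.

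The files hold no fragment counts, so total counts per library are not given directly. Relative depth was estimated from the ratio most often found between the values of rows under 1 FPKM in 2 libraries. Against OP50 it was 1.18 at 4 h, 1.23 at 8 h, 1.14 and 1.15 at 12 h, 1.21 at 17 h, and 1.25 and 1.39 at 22 h. Between 9841 and 10458 rows reached 1 FPKM in a library.

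The test was limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step, on log2(FPKM + 1) of rows with a mean of at least 1 FPKM over the libraries used. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. A model with 1 mean for each of the 6 groups of bacterium and time gave PA14 22 h against OP50 22 h and PA14 22 h against PA14 12 h. Its spread came from the 12 h and 22 h pairs, and the lone OP50 library was assumed to vary like them. A straight line in hours through the 7 PA14 libraries gave the time trend, and a quadratic term gave the curvature. Earlier PA14 times were not tested against OP50, since bacterium and time differed together.

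Gene lists, tests and naming rules were fixed before the data were examined. The lists covered defence genes (p38 pathway effectors and markers of the P. aeruginosa response, surveillance genes around ZIP-2, immune regulators, lysozymes, C-type lectins, antimicrobial peptides, the intracellular pathogen response, F-box and MATH genes), stress and detoxification (cytochrome P450, UDP-glucuronosyltransferases with glutathione S-transferases, SKN-1 targets, both unfolded protein responses, heat shock, DAF-16 targets, iron and metals), metabolism and housekeeping (fat metabolism, digestive proteases, ribosomal proteins, histones, oxidative phosphorylation, mitochondrial genome, proteasome, lysosome and autophagy, nuclear hormone receptors), reproduction (vitellogenins, oocyte and eggshell, germline, sperm, embryo), collagens, neuropeptides, and markers of intestine, muscle, pharynx, neurons and epidermis. In the lists each name was used once, by its row with the highest mean, and joined rows were left out. Lists with at least 5 measured members were tested with camera (preset correlation 0.01), which compares a list with the other genes, and with fry, which asks whether its members move on balance one way. Members past the threshold were counted after adjustment over all genes and adjusted over the list alone.

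Named genes were the 8 most raised and the 8 most lowered single-gene rows past the threshold in each of the main comparisons, with both PA14 22 h libraries on the same side of OP50, or with a slope of the same sign without each library in turn. For the other comparisons it was 4 per direction, or the 5 rows with the smallest p where none passed. Up to 3 called members with the largest change were named from each list, and irg-1, irg-4, irg-5, T24B8.5, clec-60, hsp-4, vit-2, hsp-16.2 and gst-4 were always named. A rule chosen after seeing the data set aside 143 rows that were at 0 in at least 1 library and at 10 FPKM or more in another. These rows stayed in the counts of called genes but are given as values without a fold, were left out of the lists, and were replaced by the next genes of the naming rule.

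The alternatives were a pseudocount of 0.1, no filter or a mean FPKM filter of 5, median ratio rescaling, quantile normalization, robust empirical Bayes, fewer or pooled libraries, other time scales, each library left out in turn, and an estimated correlation for the lists. Leaving out rows listed at 0 or joined rows, and putting such members back into the lists, was added later. The test was checked on simulated data, in which known changes were added to random normal values with the mean and the spread of measured rows of like level. Only rows with a mean log2 value above that of 5 FPKM were changed, so recovery in lower rows was not measured. The simulated OP50 library had the same spread as the PA14 libraries, so that assumption was not checked. Of changes of 1, 2 and 3 on the log2 scale, PA14 22 h against OP50 22 h recovered 22.4%, 62.7% and 75.8%, with 5 false calls among 112. The trend recovered 64.2%, 82.1% and 97.0%, with 7 false calls among 169, and 22 h against 12 h recovered 34.3%, 82.1% and 98.5%, with 6 false calls among 149. The simulated trends were exact straight lines, and the simulated spread was that of the 12 h and 22 h pairs. Departures from a line and shifts of whole libraries were absent, so recovery and false calls of the trend were not checked under them. A simulated shift of 1 list was called, and 0 of 39 other lists were. The simulated genes were independent and the lists random, whereas the correlation estimated for the measured sperm list over time was 0.59. False calls of lists with correlated members were therefore not checked. Other tests and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.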

Results

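The data were poly(A) RNA profiles of whole N2 worms, in 7 libraries from a PA14 infection between 4 and 22 h and 1 library from OP50 at 22 h. At 12 h and at 22 h on PA14 n was 2, and the other groups had no replicate. The FPKM of a library summed to between 633847 and 723570. The 10 rows with the highest values held 5.59% of this sum on OP50 and 10.4% in PA14 22 h replicate 1. Across 10490 genes, the log2 values of the 12 h pair correlated with an r of 0.966 and those of the 22 h pair with an r of 0.970, where genes are not independent replicates. The r between OP50 and PA14 22 h was 0.891 for replicate 1 and 0.897 for replicate 2. The log2 difference between the 12 h libraries had an SD of 0.59 and exceeded 1 in 469 genes, while the SD was 0.52 for the 22 h libraries, with 137 genes past 1.

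The question of the first comparison was which genes differ between worms on PA14 and on OP50 at 22 h. The gene F35E12.5 (now irg-5, a secreted CUB-like protein of the intestinal infection response, V, 13737010 to 13738474) rose from 1.79 FPKM on OP50 to 286 ± 187 FPKM (SD, n = 2) on PA14, a log2 change of 6.51 (SE 0.63, adjusted p = 0.010). Expression of dod-24, another CUB-like gene (IV, 12940106 to 12941354), rose from 26.7 to 1065 ± 108 FPKM, a log2 change of 5.26 (SE 0.19, adjusted p = 0.00094). The C-type lectin clec-67 (IV, 3922165 to 3925039) rose from 4.16 to 103 ± 10.4 FPKM, by 4.33 (SE 0.18) on the log2 scale, and the lysozyme gene lys-2 (V, 10280307 to 10281474) from 166 to 2187 ± 733 FPKM, by 3.67 (SE 0.34). In the opposite direction, the lysozyme gene ilys-5 (X, 6533490 to 6536840) dropped from 1130 to 10.4 ± 1.14 FPKM, a log2 change of -6.64 (SE 0.25, adjusted p = 0.0011). Acyl-CoA dehydrogenase acdh-1, an enzyme of the propionate shunt (I, 6497436 to 6499560), dropped from 571 to 6.94 ± 0.474 FPKM, a log2 change of -6.17 (SE 0.18, adjusted p = 0.00080). Without the filter on low FPKM, F35E12.5 and lys-2 were not called.

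**Figure D1:**
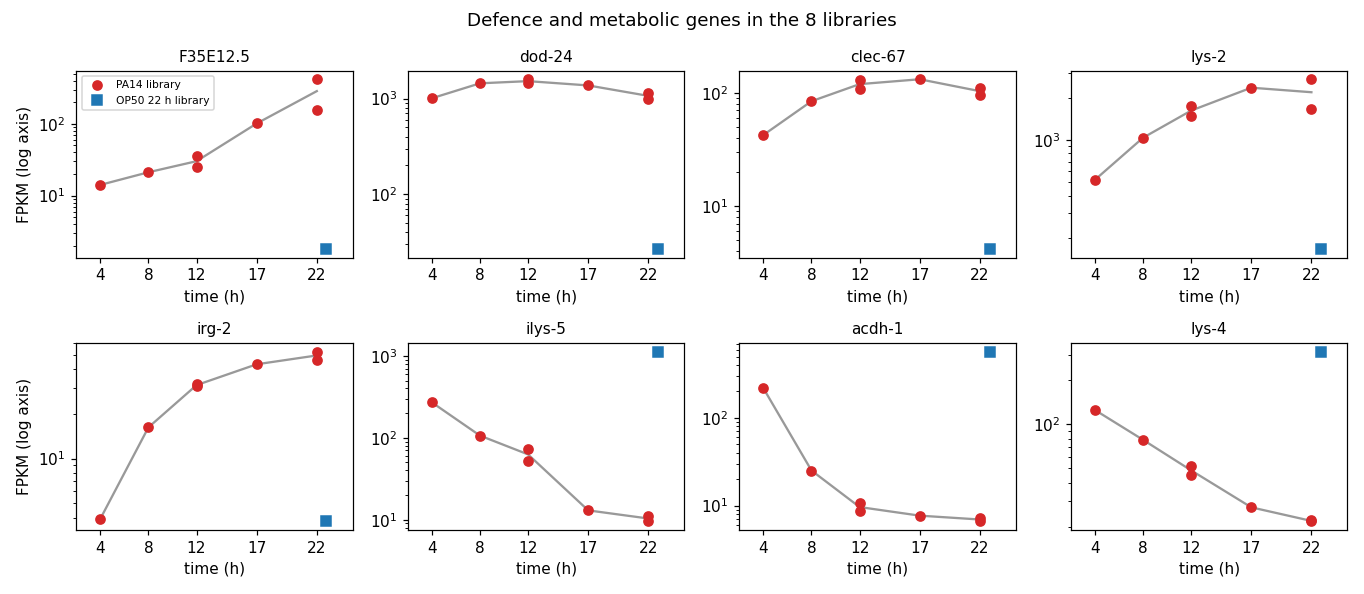
FPKM (log axis) of 8 genes against time (h). Red points are PA14 libraries, the grey line runs through the mean at each time, and the blue square is the OP50 library at 22 h, set slightly to the right; on OP50 the value of F35E12.5 was 1.79 FPKM and that of ilys-5 was 1130 FPKM, beyond all 7 PA14 libraries in each case.

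Several further genes rose on PA14 by more than 5 on the log2 scale. B0024.4 was at 447 ± 40.6 FPKM on PA14 and 5.63 FPKM on OP50 (log2 change 6.07, SE 0.28). C50F7.5 had 2 rows, which changed by 5.67 (SE 0.21) and 5.65 (SE 0.30), and dod-21 was at 44.3 ± 2.13 FPKM on PA14 and 0.0607 FPKM on OP50. T24C4.4 rose by 5.29, the lectin genes clec-4 and clec-174 by 5.58 and 5.25, and the infection response gene irg-3 by 5.21. The row that joins T24A6.7 with irg-1, a reporter gene of translation surveillance, rose from 1.79 to 129 ± 17.5 FPKM (log2 change 5.53, SE 0.19). Of the other always named defence genes, F08G5.6 (now irg-4) rose from 6.15 to 76.4 ± 32.6 FPKM and T24B8.5 from 38.8 to 121 ± 9.88 FPKM, by 3.37 and 1.62 on the log2 scale. Among the genes that fell most were F15E6.4 (log2 change -5.92, SE 0.72), T13F3.6 (-5.06, SE 0.31), T22B7.7 (-4.70, SE 0.63), D1086.3 (-4.0, SE 0.50), the transporter gene pmp-5 (-3.94, SE 0.22) and the collagen gene col-17 (-3.93, SE 0.25). Of the genes in this paragraph, clec-4, F15E6.4, T22B7.7, D1086.3 and T24B8.5 were not called without PA14 22 h replicate 1, with adjusted p between 0.073 and 0.11, and those other than clec-4 were not called without replicate 2 either, with adjusted p between 0.052 and 0.070. That of T24B8.5 was also lost with all 7 PA14 libraries and time as a line.

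Of 13 measured p38 pathway effectors and markers of the P. aeruginosa response, 11 rose and 0 fell, and 13 rose adjusted over the list alone (median log2 change 3.81). Members could enter the list as markers of the response to this pathogen, so its rise does not single out the p38 pathway. The list lay above the other genes in camera (adjusted p = 6.2e-11, adjusted p = 0.78 with an estimated correlation). Markers of the intestine, the tissue in which these genes are expressed, moved the same way to a smaller extent. Of these, 4 of 12 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 1.03 and an adjusted p of 0.10. They included the protease gene asp-1, also a digestive protease of the lists (2.62, SE 0.40), the intermediate filament gene ifc-2 (2.07, SE 0.39) and the transcription factor gene elt-7 (1.42, SE 0.27). Among 25 immune regulators 4 rose and 0 fell (9 and 0 adjusted over the list alone), and the list was called (adjusted p = 0.0035, adjusted p = 0.78 with an estimated correlation). The bZIP transcription factor gene cebp-1 rose by 3.08 (SE 0.23), the MAP kinase phosphatase gene vhp-1 by 1.30 (SE 0.20), and tir-1, which encodes the adaptor upstream of the p38 cascade, by 1.05 (SE 0.19). All 4 measured surveillance genes rose, among them F11D11.3 (4.84, SE 0.29) and F15B9.6 (3.47, SE 0.35). So did the 3 measured genes of the intracellular pathogen response, skr-5 (2.63), skr-3 (2.18) and cul-6 (1.62), which are subunits of ubiquitin ligases. Without PA14 22 h replicate 1 the calls of asp-1, ifc-2, elt-7, vhp-1, tir-1, F15B9.6, skr-5 and cul-6 were lost (adjusted p between 0.055 and 0.18), and without replicate 2 those of ifc-2, elt-7, vhp-1, tir-1, skr-5 and cul-6 (between 0.056 and 0.16). The calls of asp-1 and elt-7 were also lost without either 12 h library (between 0.052 and 0.098), that of asp-1 with only the 3 libraries at 22 h, and that of elt-7 with quantile normalization.

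Families of defence genes moved both ways. Of 56 C-type lectins 20 rose and 8 fell, and adjusted over the list alone 23 rose and 10 fell (adjusted p = 0.032, adjusted p = 0.78 with an estimated correlation). The call of this list was lost without PA14 12 h replicate 1 (adjusted p = 0.062) and without replicate 2 (0.058). Of 8 lysozymes 4 rose and 2 fell, by either adjustment. Their median change was 1.17 and their mean 0.02, fry pointed down, and the list was not called (adjusted p = 0.28). The lysozyme gene lys-4 fell from 315 to 21.9 ± 0.229 FPKM. Of 40 antimicrobial peptides 4 rose and 6 fell (5 and 10 adjusted over the list alone). The saposin-like gene spp-18 rose by 2.41 (SE 0.13), whereas spp-4 fell by 2.44 (SE 0.26) and the caenacin gene cnc-2 fell by 3.09 (SE 0.36), the last 2 of these not called without either 22 h library (adjusted p between 0.070 and 0.097). Of 126 F-box and MATH genes 17 rose and 3 fell (28 and 5 adjusted over the list alone), with a median of -0.02 and a mean of 0.17. The largest changes among them were those of fbxa-128 (3.52), fbxa-72 (-3.10) and fbxa-74 (2.90), the last 2 of them not called without PA14 22 h replicate 1 (adjusted p = 0.057 and 0.052).

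Of 26 cytochrome P450 genes 2 rose (5 rose and 1 fell adjusted over the list alone), cyp-13A5 to 12.7 ± 6.27 FPKM from 0.0006 and cyp-37B1 by 2.55. Of 41 UDP-glucuronosyltransferase and glutathione S-transferase genes 6 rose and 2 fell (6 and 5 adjusted over the list alone), with gst-38 at 4.90 (SE 0.30), ugt-31 at 3.26 and ugt-17 at -2.85. The same gst-38 was the 1 call among 15 SKN-1 targets (5 rose and 1 fell adjusted over the list alone). The SKN-1 reporter gene gst-4 was on 2 rows, at 8.35 and 4.54 FPKM on OP50, and was not called on either (log2 change -0.91 and -0.72). Heat shock genes had 2 rises and 1 fall among 11 (3 and 1 adjusted over the list alone), hsp-12.6 at 3.31 (SE 0.24), hsp-17 at 1.86 and hsp-43 at -1.72. The value of hsp-16.2 was 4.41 FPKM on OP50 and 6.48 ± 1.72 on PA14, not called. In the endoplasmic reticulum list, crt-1 (calreticulin) was the 1 call among 11, a rise of 1.43, by either adjustment. The endoplasmic chaperone gene hsp-4 was found only on a row joined with haf-2 and msra-1, which fell by 1.05 (SE 0.14). Of 6 mitochondrial unfolded protein response genes 1 fell, ubl-5 (-0.81), and 4 fell adjusted over the list alone. That list lay below the other genes (median -0.57, adjusted p = 0.0064, adjusted p = 0.78 with an estimated correlation). Of 12 DAF-16 targets 1 rose (hsp-12.6) and 2 fell, sodh-1 by -3.59 and icl-1 by -2.14 (1 and 3 adjusted over the list alone), and of 12 iron and metal genes 2 rose by either adjustment, cdr-1 (1.54) and cdf-2 (1.45). Without PA14 22 h replicate 1 the calls of cyp-13A5, cyp-37B1, ugt-17, hsp-17, hsp-43, crt-1, the hsp-4 row, ubl-5, icl-1, cdr-1 and cdf-2 were lost (adjusted p between 0.052 and 0.19). Without replicate 2 those of hsp-43, crt-1, the hsp-4 row, ubl-5, icl-1, cdr-1 and cdf-2 were lost (between 0.070 and 0.16), and without a 12 h library those of crt-1 and cdr-1 (between 0.054 and 0.066). Quantile normalization ended the calls of cdr-1 and cdf-2, leaving out joined rows that of cdr-1, and using only the 3 libraries at 22 h that of crt-1.

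Among 30 fat metabolism genes 4 rose and 6 fell (5 and 6 adjusted over the list alone), including acdh-1, the desaturase gene fat-5 (-2.68) and the lipase gene lipl-2 (2.22). Of 10 digestive proteases 2 rose and 4 fell (4 and 4 adjusted over the list alone), with a median of -0.32 and a mean of 0.35. The cathepsin B-like gene cpr-3 rose by 4.89 (SE 0.22) and cpr-1 fell by 2.53 (SE 0.18). Of 103 nuclear hormone receptors 13 rose and 2 fell (16 and 2 adjusted over the list alone), and 83 had a change above 0 (adjusted p = 2.9e-05, adjusted p = 0.78 with an estimated correlation). They included nhr-112 (2.71), nhr-114 (-2.47) and nhr-6 (2.16). Collagens fell in 26 of 90 cases and rose in 0, and adjusted over the list alone 33 fell and 3 rose (adjusted p = 0.0012, adjusted p = 0.78 with an estimated correlation). The cuticle collagen genes sqt-1 and col-101 fell by 3.81 each and col-41 by 3.37. Epidermis markers moved with them in 2 of 15 cases, both collagens, rol-6 (-2.79) and col-19 (-1.75), by either adjustment, while the median of that list was 0.31. Without PA14 22 h replicate 1 the calls of fat-5, lipl-2, nhr-112, nhr-114, nhr-6, col-101, col-41, rol-6 and col-19 were lost (adjusted p between 0.055 and 0.14), and without replicate 2 those of fat-5, lipl-2, nhr-114, nhr-6, col-101 and col-19 (between 0.059 and 0.10). That of col-41 was also lost with a pseudocount of 0.1.

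Lists of the germ line showed shifts without many single calls. Of 21 oocyte and eggshell genes 1 fell, perm-1 (-0.82), and 0 adjusted over the list alone (adjusted p = 0.022, adjusted p = 0.78 with an estimated correlation). Of 15 germline genes 1 fell, the helicase gene glh-1 (-0.59), and 0 adjusted over the list alone, and all 15 had a change under 0 (adjusted p = 0.0035, adjusted p = 0.78 with an estimated correlation). Sperm genes were called as a list in the other direction (median 0.39, adjusted p = 0.0035, adjusted p = 0.78 with an estimated correlation), with 42 of 44 members above 0, while 0 were called by either adjustment in limma and 6 had an unadjusted p under 0.05. Under quantile normalization the median of the sperm list was 0.13 and the call was lost, as was that of the oocyte list. Without PA14 22 h replicate 1 the sperm list was not called either (adjusted p = 0.064), and the largest change in it was that of msp-33, from 1.09 FPKM on OP50 to 2.95 ± 0.834 on PA14. Of 17 embryo genes elt-7 rose and pal-1 fell (-1.12), by either adjustment. The 1 measured yolk gene, vit-1, fell from 866 to 69.7 ± 21 FPKM. The rows of the other yolk genes were at 0 on OP50 and had overflow lower bounds, so they give no check of this fall. The calls of perm-1, glh-1, pal-1 and vit-1 were lost without either 22 h library (adjusted p between 0.075 and 0.19), and those of perm-1 and glh-1 also without either 12 h library (between 0.0502 and 0.0745). That of glh-1 was lost as well with median ratio rescaling, without joined rows and with only the 3 libraries at 22 h, and those of glh-1 and pal-1 with all 7 PA14 libraries and time as a line.

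Pharynx markers were called as a list (11 of 11 above 0, median 1.30, adjusted p = 0.011, adjusted p = 0.78 with an estimated correlation) with 0 members called by either adjustment in limma and 6 at an unadjusted p under 0.05, the largest value being that of phat-5 (0.349 FPKM on OP50 and 7.38 ± 0.488 on PA14). Neuropeptides were called as well (median 0.34, adjusted p = 0.032, adjusted p = 0.78 with an estimated correlation), with a rise of the insulin-like gene ins-11 (3.21) and a fall of flp-6 (-2.92) among 38, by either adjustment, and the call of the list was lost with quantile normalization. Of 16 neuron markers 1 rose, ric-19 (1.33), by either adjustment (adjusted p of the list 0.051), and of 13 muscle markers 1 fell, pat-10 (-1.07), with a median of 0.03 and a mean of -0.01. Proteasome genes lay lower as a list (median -0.24, adjusted p = 0.045, adjusted p = 0.78 with an estimated correlation), and rpn-8 (-1.14) was the 1 call of 17 by either adjustment. This list was not called without PA14 12 h replicate 1 or 2 (adjusted p = 0.059 and 0.058) or without 22 h replicate 2 (0.21), nor with quantile normalization. Oxidative phosphorylation (14 members) and ribosomal proteins (46 members) had 0 calls by either adjustment in limma, 3 and 2 members at an unadjusted p under 0.05, and medians of -0.20 and 0.26. Their largest changes were those of asb-1 (136.8 ± 0.802 FPKM on PA14, 216 on OP50) and rpl-11.2 (742 ± 204 and 307 FPKM). Of 17 histones his-71 rose (1.21), by either adjustment, and of 25 lysosome and autophagy genes 2 rose, lgg-2 (0.88) and atg-4.1 (0.87), and 0 adjusted over the list alone. Without PA14 22 h replicate 1 the calls of ins-11, flp-6, ric-19, pat-10, rpn-8, his-71, lgg-2 and atg-4.1 were lost (adjusted p between 0.052 and 0.22), and without replicate 2 the same calls but for ins-11 (between 0.070 and 0.14). Those of lgg-2 and atg-4.1 were also lost without PA14 12 h replicate 2 (0.062 and 0.052), and that of lgg-2 without 12 h replicate 1 (0.060) and with only the 3 libraries at 22 h. Quantile normalization ended the call of ric-19.

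In limma 1169 of 10490 genes were called between PA14 and OP50 at 22 h, 746 higher and 423 lower on PA14, of which 243 were joined rows. Without PA14 22 h replicate 1 the count was 200, and without replicate 2 it was 304. Without the filter on low FPKM 666 genes were called, 240 higher and 426 lower, of which 263 were among the 1169, and 49 of the 80 named calls were lost. The paragraphs above give this loss only for F35E12.5 and lys-2. It also covered clec-4, F15E6.4, T22B7.7, D1086.3, T24B8.5, asp-1, ifc-2, elt-7, F15B9.6, skr-5 and cul-6, among others. In the lists, camera called 12 of 33 with the preset correlation and 0 with an estimated correlation, and fry called 1, the oocyte list. Leaving out a 22 h library of PA14 left 1 library on each side and 1 residual degree of freedom in place of 2. No named gene reversed its direction in such a fit. The log2 change without replicate 1 and without replicate 2 was 1.28 and 1.57 for crt-1, and 1.69 and 2.46 for ifc-2. A call lost there does not by itself show that a change rested on 1 library. With 1 library on OP50, a difference of that library from other OP50 cultures could not be separated from the bacterium.

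**Figure D2:**
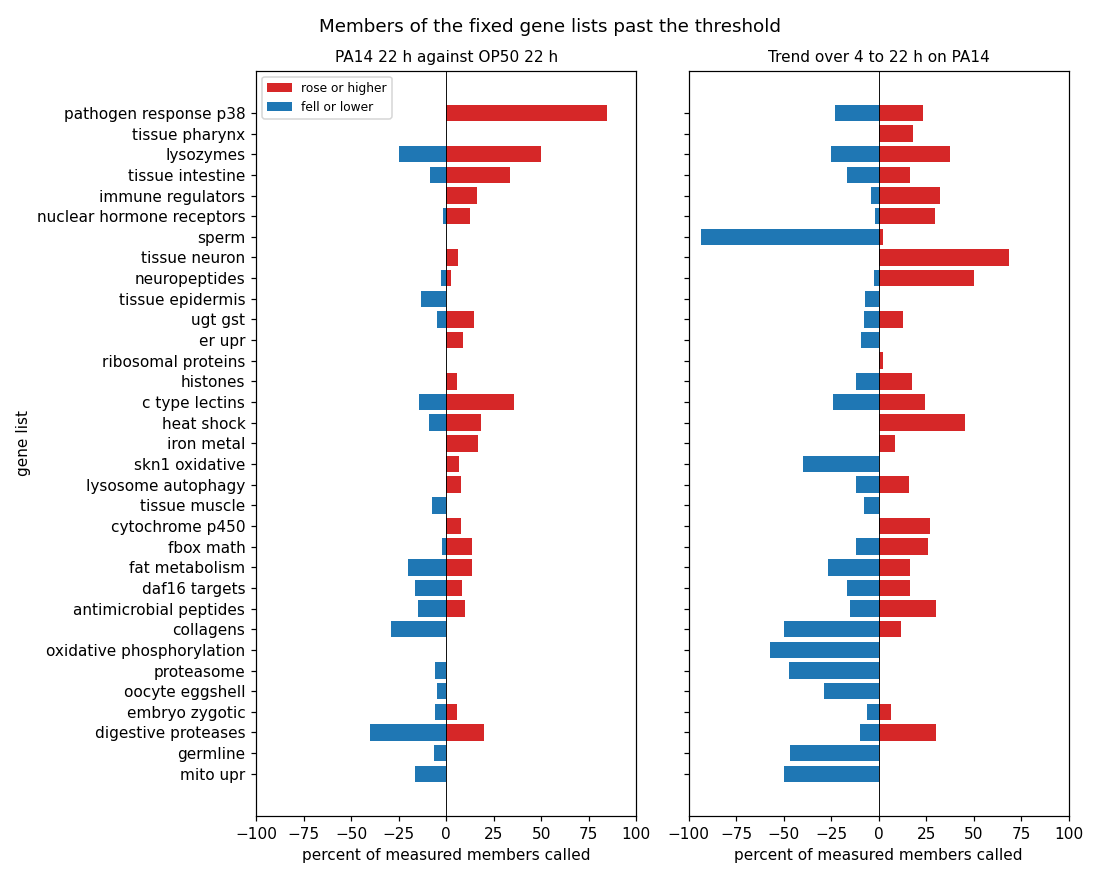
Percent of measured members called (x axis, rises to the right in red and falls to the left in blue) for each fixed gene list (y axis), between PA14 and OP50 at 22 h on the left and over the PA14 hours on the right. Lists with at least 5 measured members are drawn. The list of p38 effectors and response markers had 11 of 13 members called on the left, and the sperm list 42 of 45 falling on the right.

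The time trend asked which genes moved steadily between 4 and 22 h on PA14. Major sperm protein transcripts fell together: msp-152 (II, 4933027 to 4933410) was at 64.6 FPKM at 4 h and 3.31 ± 1.07 FPKM (SD, n = 2) at 22 h, a fitted change over 18 h of -3.86 on the log2 scale (SE 0.32, adjusted p = 0.00093). The adult cuticle collagen gene col-19 (X, 421707 to 422691) went from 1929 to 186 ± 7.18 FPKM (-3.36, SE 0.24, adjusted p = 0.00081). Levels of the neuropeptide gene flp-15 rose from 10 to 71.0 ± 18.7 FPKM (3.24, SE 0.61, adjusted p = 0.0094). Single defence genes rose too, though the p38 effectors with the response markers, and the lectins, went both ways as lists. F35E12.5 was at 14.1 FPKM at 4 h (4.36, SE 0.53). The infection response gene irg-2 was at 3.92 FPKM at 4 h and 49.6 ± 4.42 FPKM at 22 h (2.82, SE 0.54), and cebp-1 at 9.66 and 56.3 ± 12.4 FPKM (2.35, SE 0.36). Without the 4 h library the fitted change of irg-2 was 1.71.

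**Figure D3:**
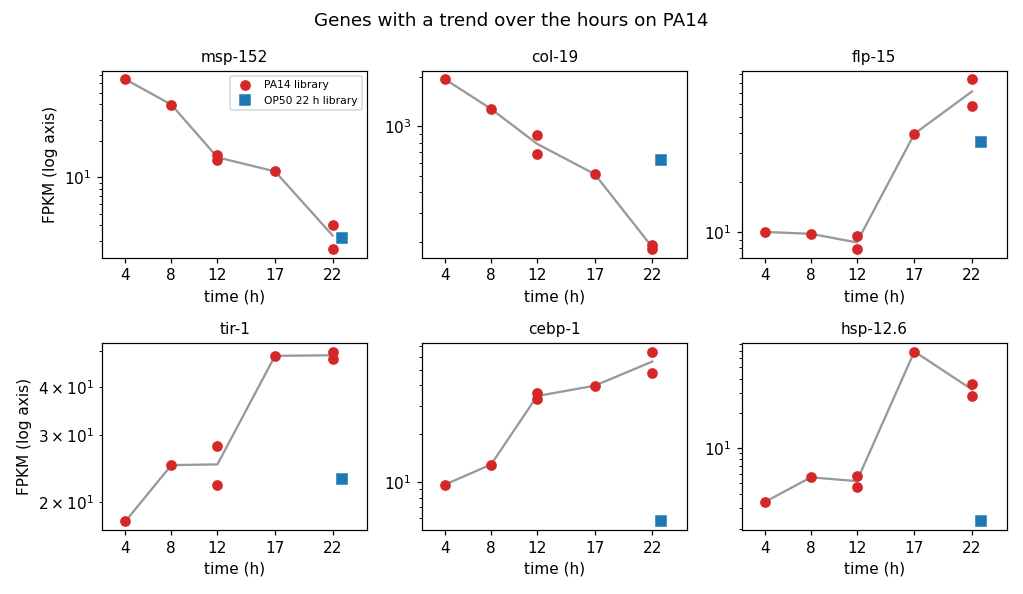
FPKM (log axis) of 6 genes against time (h). Red points are PA14 libraries, the grey line runs through the mean at each time, and the blue square is OP50 at 22 h, set slightly to the right; msp-152 lay at 3.14 FPKM on OP50, between the 2 PA14 libraries of 22 h, and hsp-12.6 at 2.31 FPKM, below all 7 PA14 libraries.

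The steepest rises were those of ram-2, a collagen gene (fitted change over 18 h 5.11, SE 1.12), col-74 (4.96, SE 1.48), C08E3.13 (4.84, SE 0.86), the neuropeptide-like gene nlp-39 (4.83, SE 0.46), F08G2.5 (4.79, SE 0.63), the surveillance gene F11D11.3 (4.52, SE 0.40) and W02D7.11 (4.46, SE 0.98). The steepest falls were those of the collagen genes col-129 (-5.46, SE 0.47), col-139 (-5.30, SE 0.52), col-81 (-4.95, SE 0.62), col-133 (-4.37, SE 0.75) and col-124 (-4.35, SE 0.24), the lysozyme gene ilys-5 (-4.64, SE 0.38), R09E10.6 (-4.63, SE 0.63) and C45B2.1 (-4.38, SE 0.56). The calls of 3 of the genes that rose were lost when single libraries were left out. That of ram-2 was lost without PA14 8 h or 22 h replicate 1 (adjusted p = 0.051 and 0.069). That of W02D7.11 was lost without 4 h, 8 h or 22 h replicate 1 (0.059, 0.051 and 0.052), and that of col-74 without 4 h, 8 h, 12 h replicate 1 or either 22 h library (between 0.059 and 0.17). Their log2 slopes in these fits stayed between 0.234 and 0.279 per h, so the calls were lost rather than the rises. Log2 hours ended the call of ram-2 as well, and robust empirical Bayes and the mean at each time that of col-74.

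Sperm genes fell in 42 of 45 cases and 1 rose (43 and 1 adjusted over the list alone; adjusted p = 1.1e-22, adjusted p = 0.53 with an estimated correlation), with msp-64 at -3.85 and msp-40 at -3.73 beside msp-152. Germline genes fell in 7 of 15 cases, 9 adjusted over the list alone (adjusted p = 0.0014, adjusted p = 0.69 with an estimated correlation), among them glh-1 (-0.88), him-3 (-0.80) and syp-3 (-0.77). Of 21 oocyte and eggshell genes 6 fell, 8 adjusted over the list alone (adjusted p = 0.0023, adjusted p = 0.77 with an estimated correlation), with perm-1 (-1.18), lin-41 (-0.77) and cgh-1 (-0.76). Of 16 embryo genes pal-1 fell (-1.21) and tbx-11 rose (1.18), 0 adjusted over the list alone. Collagens fell in 42 of 84 cases and rose in 10, 45 and 12 adjusted over the list alone (adjusted p = 0.00022, adjusted p = 0.69 with an estimated correlation), and this list was not called without the 4 h library (adjusted p = 0.066). Epidermis markers did not fall with them as a list, since 12 of 14 had a slope above 0 (median fitted change over 18 h 0.81, adjusted p = 0.26 in camera). The 1 call by either adjustment was the fall of col-19, itself a collagen. The calls of glh-1, him-3, syp-3, lin-41, cgh-1, pal-1 and tbx-11 were lost without the 4 h library (adjusted p between 0.059 and 0.22), and all of these but lin-41 also without the 8 h library (between 0.054 and 0.13). Leaving out a 22 h library ended the calls of glh-1, syp-3, cgh-1 and pal-1 with either one (between 0.073 and 0.19), that of him-3 with replicate 1 (0.069), and those of lin-41 and tbx-11 with replicate 2 (0.051 and 0.15). Without PA14 12 h replicate 1 syp-3, cgh-1 and tbx-11 were not called (between 0.052 and 0.069), and without 17 h tbx-11 was not (0.063). The fitted change of syp-3 was -0.50 without 22 h replicate 1, and the calls of syp-3 and cgh-1 were also lost with either rescaling, with log2 hours and with the mean at each time. The same time settings ended the call of glh-1, quantile normalization those of pal-1 and tbx-11, and the mean at each time that of pal-1.

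Of 16 neuron markers 11 rose, 12 adjusted over the list alone (adjusted p = 7.3e-05, adjusted p = 0.53 with an estimated correlation), among them unc-31 (2.0), egl-3 (1.94) and tbb-4 (1.84), which encode a secretion factor, a neuropeptide convertase and a tubulin. Neuropeptide genes rose alongside, 19 of 38 with 1 fall by either adjustment (adjusted p = 9.0e-06, adjusted p = 0.69 with an estimated correlation). They included the insulin-like genes ins-11 (3.56, SE 0.55) and ins-18 (2.88, SE 0.51). Of 105 nuclear hormone receptors 31 rose and 2 fell by either adjustment (adjusted p = 7.4e-06, adjusted p = 0.53 with an estimated correlation), among them nhr-112 (1.67), nhr-3 (1.42) and nhr-6 (1.28). Pharynx markers had 2 rises among 11, phat-5 (2.78) and pha-4 (1.5), and 1 adjusted over the list alone. Muscle markers had 1 fall among 13, pat-10 (-0.69), by either adjustment. Of 12 intestine markers ifc-2 (0.99) and ges-1 (0.77) rose and 2 fell, including lbp-6 (-1.32), and 5 rose and 2 fell adjusted over the list alone. Without the 4 h library the calls of unc-31, tbb-4, nhr-112, nhr-6, phat-5, pha-4, pat-10, ifc-2 and ges-1 were lost (adjusted p between 0.073 and 0.20), and without the 8 h library those of unc-31, egl-3, tbb-4, nhr-6, phat-5, pha-4, ifc-2 and ges-1 (between 0.053 and 0.12). Without 22 h replicate 1 those of egl-3, tbb-4, nhr-6, phat-5, pha-4, ifc-2 and ges-1 were lost (between 0.068 and 0.16), and without replicate 2 those of unc-31, egl-3, tbb-4, phat-5, pha-4 and pat-10 (between 0.056 and 0.13). The calls of tbb-4, pha-4 and ifc-2 were also lost without 12 h replicate 1 (between 0.054 and 0.065), and that of ifc-2 without 17 h (0.056). Quantile normalization ended the calls of unc-31, tbb-4 and pha-4, log2 hours those of unc-31 and egl-3, and the mean at each time those of unc-31, egl-3 and ges-1.

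Immune regulators rose in 8 of 25 cases and 1 fell by either adjustment (adjusted p = 0.0035, adjusted p = 0.69 with an estimated correlation). Besides cebp-1 they included the homeobox gene egl-5 (2.01, SE 0.30) and tir-1 (1.46, SE 0.23), the latter from 17.8 FPKM at 4 h to 48.6 ± 1.59 at 22 h. The p38 effectors and response markers went both ways over the hours, 3 up and 3 down of 13 by either adjustment (adjusted p = 0.50). There were falls of F55G11.2 (-2.49) and C32H11.1 (-1.98) beside the rise of F35E12.5. Of the 4 surveillance genes 3 rose, F15B9.6 by 2.27, and the row of irg-1 with T24A6.7 rose by 2.98. In the intracellular pathogen response 3 of 3 rose, skr-5 by 2.28 and skr-3 and cul-6 by 1.08 each. Of 8 lysozymes 3 rose and 2 fell (4 and 2 adjusted over the list alone), lys-3 by 2.05 and lys-4 by -2.44, with a positive median slope, a negative mean slope and fry pointing down. Of 58 C-type lectins 14 rose and 14 fell (16 and 15 adjusted over the list alone), with clec-266 (3.92), clec-47 (-3.61) and clec-218 (-2.52) changing most, and fry pointed down against a median above 0. The row joining ZK666.13 with clec-60 rose by 1.49, to between 1.80 and 2.48 FPKM at 22 h. Of 40 antimicrobial peptides 12 rose and 6 fell, 13 and 6 adjusted over the list alone (adjusted p = 0.030, adjusted p = 0.71 with an estimated correlation), and this list was not called without 12 h replicate 2 (adjusted p = 0.10) or with quantile normalization. The defensin-like gene abf-2 rose by 2.7, nlp-29 rose by 1.96 and fipr-10 fell by 1.96. Of 127 F-box and MATH genes 33 rose and 15 fell (36 and 16 adjusted over the list alone), among them fbxa-30 (1.66), fbxa-72 (-1.60) and bath-26 (-1.55). For F08G5.6 and T24B8.5 the fitted changes were 0.76 and 0.98, not called. Without the 4 h library the calls of C32H11.1, F15B9.6, cul-6, clec-266, clec-218, abf-2, fipr-10 and fbxa-72 were lost (adjusted p between 0.058 and 0.18), without 8 h those of C32H11.1, clec-218, abf-2 and fbxa-72 (between 0.060 and 0.086), and without 12 h replicate 1 that of abf-2 (0.057). Without 22 h replicate 1 those of cul-6, clec-218, abf-2, fbxa-72 and bath-26 (between 0.051 and 0.10) and without replicate 2 those of C32H11.1, clec-218 and abf-2 (between 0.055 and 0.13) were lost. Without 4 h the fitted changes were 1.94 for the irg-1 row, -1.43 for clec-218 and -0.77 for fbxa-72. The mean at each time ended the calls of abf-2 and fbxa-72, and log2 hours or quantile normalization that of abf-2.

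Oxidative phosphorylation genes fell in 8 of 14 cases, 10 adjusted over the list alone (adjusted p = 0.0010, adjusted p = 0.69 with an estimated correlation), with asb-1 (-0.94), nuo-6 (-0.74) and ucr-2.3 (-0.71). Proteasome genes fell in 8 of 17 by either adjustment (adjusted p = 0.0031, adjusted p = 0.69 with an estimated correlation), with rpn-8 (-1.23), pbs-3 (-0.87) and rpt-2 (-0.74), and the list was not called with quantile normalization. Of 6 mitochondrial unfolded protein response genes 3 fell, 5 adjusted over the list alone (adjusted p = 0.046, adjusted p = 0.69 with an estimated correlation), namely hsp-60 (-0.87), hsp-6 (-0.72) and tomm-20 (-0.54). That list was not called without 4 h, either 12 h library or 22 h replicate 2 (adjusted p between 0.0502 and 0.076), nor with quantile normalization or with the members on joined rows added. The call of hsp-60 lay close to the threshold (adjusted p = 0.049). It was lost with a pseudocount of 0.1, with no filter or a filter of 5, with either rescaling, without joined rows, and with log2 hours, the rank of the time or the mean at each time. That of tomm-20 was lost with quantile normalization, log2 hours and the mean at each time. Heat shock genes rose in 5 of 11 cases by either adjustment (adjusted p = 0.011, adjusted p = 0.53 with an estimated correlation), among them hsp-12.6 (3.50, SE 0.84), hsp-16.2 (1.82, SE 0.27) and hsp-16.41 (1.31, SE 0.32). The row with hsp-4 fell by 0.88. The calls of nuo-6, ucr-2.3, pbs-3, rpt-2, hsp-60, hsp-6, tomm-20, hsp-12.6, hsp-16.41 and the hsp-4 row were lost without the 4 h library (adjusted p between 0.070 and 0.19), and those of ucr-2.3, rpt-2, hsp-60, hsp-6, tomm-20, hsp-12.6 and hsp-16.41 without 8 h (between 0.054 and 0.097). Without 22 h replicate 1 rpt-2, hsp-12.6 and hsp-16.41 were not called (between 0.065 and 0.090). Without replicate 2 ucr-2.3, pbs-3, rpt-2, hsp-60, hsp-6, tomm-20 and the hsp-4 row were not (between 0.052 and 0.16), and without 12 h replicate 1 hsp-60 and tomm-20 were not (0.071 and 0.052). Without 4 h the fitted change of the hsp-4 row was -0.53. Log2 hours ended the calls of ucr-2.3, rpt-2 and hsp-16.41, and the mean at each time those of ucr-2.3, rpt-2, hsp-12.6 and the hsp-4 row.

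Camera called none of the other lists, but fry called the SKN-1 list downward (adjusted p = 0.045, against 0.17 in camera). Of 15 SKN-1 targets 6 fell (6 fell and 1 rose adjusted over the list alone), with gst-13 (-1.44), prdx-2 (-1.21) and ptps-1 (-1.11), and the rows of gst-4 had fitted changes of -1.31 and -1.27, not called. Of 39 UDP-glucuronosyltransferase and glutathione S-transferase genes 5 rose and 3 fell (4 and 2 adjusted over the list alone), including ugt-29 (1.52) and gst-28 (-1.21), with a median under 0 where camera pointed up. Of 26 cytochrome P450 genes 7 rose (5 adjusted over the list alone), including cyp-13A5 (2.59), cyp-14A5 (2.26) and cyp-32B1 (1.40). Of 11 endoplasmic reticulum genes ckb-2 fell (-1.52) and 0 adjusted over the list alone, and of 12 DAF-16 targets 2 rose and 2 fell by either adjustment, sodh-1 by -2.96 and icl-1 by -2.25. Of 12 iron and metal genes ftn-1, a ferritin, rose (1.45), and 0 adjusted over the list alone. In fat metabolism 5 of 30 rose and 8 fell by either adjustment, with acdh-1 (-3.74), cpt-5 (-2.60) and the desaturase gene fat-6 (2.34) changing most. Of 10 digestive proteases 3 rose and 1 fell (5 and 1 adjusted over the list alone), cpr-3 by 2.55, asp-6 by 1.23 and cpr-5 by -2.39. Of 46 ribosomal protein genes rpl-11.2 rose (1.26) and 0 adjusted over the list alone. Of 17 histones 3 rose and 2 fell by either adjustment, with his-70 (-1.79), his-38 (-1.56) and his-32 (1.38). Of 25 lysosome and autophagy genes 4 rose and 3 fell by either adjustment, with atg-2 (1.05), hlh-30 (1.04) and vha-18 (-0.78), a median slope under 0 and a mean above 0. The yolk gene vit-1 had a fitted change of -1.78, not called (adjusted p = 0.0503). Among these genes, the calls of ptps-1, ugt-29, cyp-32B1, ckb-2, sodh-1, icl-1, ftn-1, acdh-1, cpr-3, asp-6, atg-2 and vha-18 were lost without 4 h and without 8 h (adjusted p between 0.053 and 0.27). Without 4 h alone those of cyp-13A5, cpt-5 and rpl-11.2 were also lost (between 0.052 and 0.074). The calls of gst-13 (0.11 and 0.051) and hlh-30 were lost without 1 or more of these early libraries too, hlh-30 without 8 h (0.073) and without either 22 h library (0.11 and 0.052). Without 22 h replicate 1 the calls of ptps-1, ugt-29, cyp-32B1, sodh-1, icl-1, acdh-1, cpr-3, asp-6, atg-2 and vha-18 were lost (between 0.054 and 0.11), and without replicate 2 those of ptps-1, ckb-2, sodh-1, ftn-1 and atg-2 (between 0.058 and 0.13). Without 12 h replicate 1 ugt-29, ftn-1 and asp-6 were not called (between 0.062 and 0.067), and without 17 h sodh-1 was not (0.051). Several of the values also rested on the 4 h library, since without it the fitted changes were -1.68 for acdh-1, -1.50 for sodh-1, -0.77 for ckb-2, 1.67 for cpr-3, 0.81 for asp-6 and 0.79 for ugt-29. Median ratio rescaling ended the call of ptps-1, quantile normalization those of ptps-1, asp-6 and ftn-1, the mean at each time those of ptps-1, ftn-1, sodh-1 and ugt-29, and log2 hours that of hlh-30.

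In limma 3312 of 10465 genes had a trend over the PA14 hours, 1571 rising and 1741 falling. The balance of directions turned with median ratio rescaling (1700 rising, 1451 falling), without the 4 h library (517 rising, 394 falling), without 22 h replicate 2 (843 rising, 805 falling) and with the mean of the libraries at each time (1097 rising, 1048 falling). The count was 911 without the 4 h library, 1342 without 8 h, 1434 without 22 h replicate 1 and 1648 without replicate 2. With a mean FPKM filter of 5 it was 2197, and with the mean of the libraries at each time 2145. Without a filter the calls of 18 named genes were lost, namely abf-2, asp-6, cgh-1, ckb-2, col-74, fbxa-72, ftn-1, glh-1, hsp-60, ifc-2, pha-4, ptps-1, sodh-1, syp-3, tbb-4, tbx-11, ugt-29 and unc-31. In the lists, camera called 13 of 33 with the preset correlation and 0 with an estimated correlation, and fry called 12. Counts of members are to be read beside the 1571 rising and 1741 falling among all 10465 genes. The counts of lysosome and autophagy genes (4 and 3 of 25), histones (3 and 2 of 17) and intestine markers (2 and 2 of 12) were near those shares. Time on PA14 and age rose together in these libraries, and OP50 was sampled at 1 time, so the trend does not separate infection from age.

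Between 12 and 22 h on PA14, the stretch with replicates on both sides, the collagen genes col-129 (IV, 12108734 to 12110439) and col-139 (V, 4652863 to 4653971) fell. The level of col-129 went from 62.8 ± 0.0817 FPKM to 10.4 ± 1.95 FPKM (SD, n = 2), a log2 change of -2.49 (SE 0.15, adjusted p = 0.026), and that of col-139 from 76.5 ± 5.30 to 14.2 ± 2.86 FPKM (-2.36, SE 0.16, adjusted p = 0.043). F35B12.9 was listed at 0 in both 12 h libraries and at 6.70 ± 0.105 FPKM at 22 h, and W06H8.16 at 0 in the libraries of 4 to 17 h and at 4.31 ± 0.304 FPKM at 22 h. In limma 13 of 10490 genes were called, 8 higher and 5 lower at 22 h, and 8 of these were rows at 0 in some libraries and high in others. Unadjusted, 2986 genes had p under 0.05. The count depended strongly on the settings. It was 34 without 12 h replicate 2, 24 without 22 h replicate 2, 40 with only the 4 libraries at 12 and 22 h, 207 without rows listed at 0 and 213 with robust empirical Bayes. With a replicate block it was 282, with a filter of 5 or quantile normalization 24, and without a filter 5, which included none of the 4 genes named here. Both collagens lost their call without any 1 of the 4 libraries at 12 and 22 h (adjusted p between 0.062 and 0.11), F35B12.9 without 12 h replicate 1 or either 22 h library (between 0.065 and 0.16), and W06H8.16 without either 12 h library (0.099 and 0.060). That of col-139 was also lost with a pseudocount of 0.1, with median ratio rescaling and without joined rows.

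Curvature was tested to find genes with a peak or a dip within the PA14 hours. In limma 0 of 10465 genes were called, and 616 had an unadjusted p under 0.05. The smallest p belonged to F35B12.9 (adjusted p = 0.077), col-149 (0.099), E03H4.8, acdh-1 and irg-2 (0.22 each), none past the threshold. The values of E03H4.8 were 8.56 FPKM at 4 h, 62.6 at 17 h and 52.8 ± 8.60 at 22 h, and those of col-149 were 25 FPKM at 4 h, 1.92 at 17 h and 5.13 ± 1.35 at 22 h. Without the 4 h library 2 genes were called, and without 17 h 1 was. There were also 2 without rows listed at 0 and 1 with robust empirical Bayes.

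Values at the earlier PA14 times lay beside those of OP50 at 22 h without a test. At 4 h dod-24 was at 1006 FPKM, irg-3 at 332 FPKM and gst-38 at 85.2 FPKM, against 26.7, 8.01 and 1.07 FPKM on OP50. By contrast irg-2 was at 3.92 FPKM at 4 h and 3.76 FPKM on OP50, F11D11.3 at 0.379 and 0.236 FPKM, and hsp-12.6 at 3.40 and 2.31 FPKM. The value of acdh-1 was 218 FPKM at 4 h, 25.1 FPKM at 8 h and 8.68 and 10.6 FPKM at 12 h, against 571 FPKM on OP50.

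Some genes past the threshold were listed at 0 in whole libraries and high in others, and no fold is given for them. They numbered 43 of the calls between PA14 and OP50 at 22 h and 16 of the trend calls. The yolk protein gene vit-5 was at 0 FPKM on OP50 and between 1063 and 1989 FPKM on PA14, and vit-4 at 0 and between 42.2 and 192 FPKM, but both zeros stood beside an overflow lower bound and were taken as failed estimates. On OP50 F21F3.6, asg-1 and ath-1 were at 0 as well, and at 22 h on PA14 they were at 301 ± 16, 119.8 ± 0.605 and 69.7 ± 2.68 FPKM. The eggshell gene cpg-1 and the ribosomal protein gene rpl-2 were at 0 in the 4 libraries of 12 and 22 h on PA14 and at 1323 and 1157 FPKM on OP50. Listed at 0 at 22 h on PA14 were also mex-5 (531 FPKM on OP50), Y51F10.2 (139 FPKM) and xnd-1 (52.3 FPKM). In the trend, cyc-1 was at 0 at 4 and 8 h and at 163 FPKM or more later, F46F11.1 at 0 at 4 h, 8 h and 12 h replicate 1 and at 17.9 FPKM or more in the other PA14 libraries, and C54C8.12 at 0 at 4 h and at 12.9 and 25.8 FPKM at 22 h. Between 12 and 22 h, ldh-1, T19B4.3 and both rows of unc-40 were at 0 in the 12 h libraries and at 54.8 ± 9.18, 38.9 ± 1.82, 47.3 ± 1.41 and 34.1 ± 6.80 FPKM at 22 h, while ZK430.7 and tag-231 were at 0 at 22 h and at 45.9 ± 1.65 and 29.3 ± 0.514 FPKM at 12 h. The yolk gene vit-2 was at 0 in all 8 libraries, and genes of the mitochondrial genome had no row of their own.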

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

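The alternatives without rows listed at 0, without joined rows, and with such members put back into the lists were chosen after seeing the data. No call of a named gene or list changed direction: of 3543 comparisons of a named gene with an alternative, 3092 kept their side of the threshold, 430 fell short of it and 21 newly passed it, and for lists it was 792, 45 and 21 of 858.

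Between PA14 and OP50 at 22 h, 1169 genes were called. Without a filter on low FPKM it was 666 (240 higher, 426 lower), of which 263 were shared with the 1169, while 20451 rather than 10490 rows were tested. The balance of directions thus depended on the filter, a mean over 8 libraries of which 7 were on PA14. A gene seen only on OP50 passes such a mean less easily than one seen across the PA14 libraries. How much this added to the change in direction was not tested. The calls of F35E12.5, F08G5.6, lys-2 and ugt-31 were lost without the filter, and under no other setting. The other settings gave between 853 genes (without joined rows) and 1579 (all 7 PA14 libraries with time as a line). Leaving out 1 library gave between 200 (without 22 h replicate 1) and 1308, with 304 without 22 h replicate 2, where 1 library stood on each side. The comparison could not be fitted without OP50. Under each alternative that gave a value for them 27 named calls were kept, among them acdh-1, ilys-5, dod-24, clec-67, cebp-1 and lys-4.

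The trend of 3312 genes became 2197 with a mean FPKM filter of 5, which tested 7264 rows, and 2145 with the mean of the libraries at each time, which left 5 values. Leaving out 1 library gave between 911 (without 4 h) and 3961 (without 12 h replicate 2). Without 8 h it was 1342, and 1434 and 1648 without 22 h replicate 1 and 2. The rising share went from 47.4% to 54% with median ratio rescaling and also passed the falling share without 4 h, without 22 h replicate 2 and with the mean at each time. Under each alternative that gave a value for them 48 named calls were kept. Joined rows had no value without joined rows, genes of low level none under the filter of 5, and the row with clec-60 none without some libraries.

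The 13 genes between 12 and 22 h became 5 without a filter, 24 with a filter of 5 and 24 with quantile normalization. The count was 213 with robust empirical Bayes, 207 without rows listed at 0, 40 with only the 4 libraries and 282 with a replicate block. The cause was not tested. The main fit had 2 residual degrees of freedom, and 2986 genes had an unadjusted p under 0.05 in limma. The 13 calls therefore do not show that few genes differed. Differences between the paired libraries did not correlate between 12 and 22 h (r -0.0056 across genes), so the block has no basis in the data. Leaving out 1 library gave between 13 and 34. For curvature 0 became 1 with robust empirical Bayes and 2 without rows listed at 0, and between 0 and 2 without 1 library; the cause was not tested.

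With an estimated correlation the called lists went from 12 to 0 against OP50 and from 13 to 0 over time. Correlated members alone do not account for this. For collagens against OP50 the estimated correlation was 0.0018, below the preset 0.01, yet the unadjusted camera p went from 0.00011 to 0.039. That setting relies on the residual degrees of freedom, 2 against OP50 and 5 over time, so its loss of calls says little about single lists. Without 1 library the called lists numbered between 10 and 15 against OP50, and between 11 and 16 over time. Quantile normalization ended the calls of the neuropeptide, oocyte, proteasome and sperm lists against OP50, and those of the antimicrobial peptide, mitochondrial unfolded protein response and proteasome lists over time; the cause was not tested. The mitochondrial list over time was also not called with members on joined rows added. Among lists not called, the median of the cytochrome P450, endoplasmic reticulum and lysosome lists over time changed sign with scaling. Scaling moved the median of all genes by less than 0.1 on the log2 scale. Fragment counts are not in the files, and the counting error of low values was not worked out from the deposited bounds.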

Other observations

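The tests of age, of the pathogen response genes and of the rows at 0 were chosen after the results were seen; those of the order of libraries and of vitamin B12 were written down first. Some genes linked to vitamin B12 and 1-carbon metabolism, picked after their values were seen, were lower on PA14 at 22 h: besides acdh-1 and pmp-5, the folate transporter gene folt-2 fell by 3.53 (SE 0.24) and the receptor gene nhr-114 fell by 2.47, while a row joining nhr-101 with nhr-68 fell by 2.01 and nhr-10 was at 14 FPKM on OP50 and at 12.5 and 14.7 FPKM at 22 h on PA14. The trend genes with a fitted change of at least 1 over 18 h numbered 1797. On a scale with the fitted 4 h value at 0 and the 22 h value at 1, OP50 at 22 h had a median position of 0.379 for the 1086 rising and 1.04 for the 711 falling genes.

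A candidate explanation for the low acdh-1 is a vitamin B12 supply that differs between the bacteria, as the propionate shunt runs when B12 is scarce. Of the other shunt genes only Y38F1A.6 had a row of its own, and it fell by 3.25 (adjusted p = 0.0053, higher on OP50 than in both PA14 22 h libraries), too few for a verdict. A row joining T05G5.5 with ech-6 fell by 1.81, and rows joining alh-8 (0.36) and F09F7.4 (-0.48) with other genes were not called. Of 7 methionine cycle genes, with a median of -0.84, 3 were called lower on PA14, fewer than the test had asked for: metr-1 (-0.82), mthf-1 (-1.1) and mel-32 (-0.84). The values of sams-1 (-1.97), ahcy-1 (-0.85) and mtrr-1 (-0.63) were also below 0 but not called, and cbs-1 was at 0.66, not called. The 4 measured genes of the canonical B12-dependent propionate pathway had a median of -0.37, with 0 called in limma and mce-1 and mmab-1 at an unadjusted p under 0.05. These values leave the explanation open. Growth on another lawn and infection change with the bacterium as well, and none was tested.

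The fall of the sperm genes may come from time in culture rather than from infection. Their OP50 position had a median of 1.15 (quartiles 1.08 to 1.19), and all 42 called genes lay nearer the 22 h end. The 52 collagens had a median of 0.647 (quartiles 0.194 to 0.902). The 10 rising ones lay near the 22 h end (0.913, quartiles 0.827 to 0.997), which may likewise reflect time in culture. For the 42 falling collagens (0.481, quartiles 0.188 to 0.803) and the neuropeptides (0.735, quartiles 0.446 to 0.852) age and infection cannot be told apart, because members lie on both sides of the middle of the scale and OP50 was sampled once.

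The pathogen response genes were higher on PA14 with a median of 3.81 against 1.03 for the 12 intestine markers. The two-sided permutation p of the difference was 0.0026. It treated 13 and 12 genes as independent, though all values came from the same libraries. The estimated correlations within the lists were 0.48 and 0.52. That p therefore does not measure the spread between cultures, and it cannot rule out a larger share of intestinal RNA. The medians show only that the list rose more than the markers in these libraries. Scaling does not account for the rise of the list, as its lowest median over the scalings was 3.75. Also open are the lone OP50 library, which any property of that culture would affect, and a food difference between the bacteria.

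Rows at 0 in some libraries and high in others may be failed estimates over a stretch of the genome. Of 36 pairs of such rows within 10000 bases, 28 shared the same libraries at 0, and the highest number in 10000 shuffles was 7. No biological explanation was tested.

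The order of the 7 PA14 libraries was compared with random ones. Of 100 orders, the real one included, 1 gave as many as 3312 trend genes, the smallest share that this test could give. The highest of the others gave 2507, with hours that correlated with the real ones at 0.911 (the median of the others was 0). It only exchanged the hours of 12 h replicate 2 and the 17 h library. Random orders thus seldom gave so many calls. The test cannot separate time from other differences that ran along with the hours. Placed along the fitted line over 10326 genes, 12 h replicate 1 lay at 12 h and replicate 2 at 15.9 h, beside 15.7 h for the 17 h library. OP50 came out at 13 h, but a library unrelated to the line is also placed near the mean PA14 hour. This value therefore gives no age for OP50. Its median position was 0.379 for rising and 1.04 for falling genes, so OP50 had no single place on the line.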
